A study of Mus musculus with 12 samples.

How the data were processed

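The series holds 12 polyA RNA-seq libraries from the brains of male C57BL/6 mice aged 10 to 12 weeks. Per the labels' protocols, the mice received 3 pairings of a tone with a foot shock of 0.7 mA, followed by an intraperitoneal injection of dexmedetomidine at 40 µg per kg, in 10 ml per kg, or of an equal volume of normal saline. Dexmedetomidine is a sedative agonist of alpha2 adrenergic receptors. The labels call the drug group "Dex", and that short form is used below. Tissue was taken 2 h after training from the prelimbic (PL) or infralimbic (IL) part of the prefrontal cortex. The labels thus give 4 groups of 3 libraries: PL saline, PL Dex, IL saline and IL Dex. The extraction protocol in the labels names prelimbic tissue in every sample, whereas 6 titles name infralimbic cortex; the titles were followed. Each sample carries a batch number from 1 to 3 that equals its sample number. The labels do not say whether the PL and IL libraries of one number came from one mouse, nor whether the samples of a group came from separate mice, so p-values measure the spread between these samples.

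The authors deposited whole-number read counts per gene, which sum to a different total in each library and carry no normalization. Per the file headers, the counts were made with featureCounts 2.0.1 on exons, summed by gene identifier, in paired-end mode and with no strand option, against the GRCm38 annotation of release 98. Per the submitters' processing notes, bcl2fastq, Trim Galore, HISAT2 and SAMtools 1.8 were also used; the notes name the genome build mm39. The 2 sources differ, and the gene coordinates in the table equal those of GRCm38, which is the build of every coordinate given here. Without strand, reads from a gene and a gene overlapping it on the other strand cannot be told apart. Of the count columns in the table, 12 matched no sample in the labels and were not used. The table lists 55421 genes, of which 55154 had a symbol in the reference gene names and 38950 had at least 1 count; 107 symbols shared by several identifiers were kept for the identifier with the largest total. All 37 mitochondrially encoded genes and all 86 genes on unplaced scaffolds had 0 counts in every library, so the mitochondrial share could not serve as a measure of RNA quality.

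Totals per library ran from 5419187 to 16530596 counts. Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 4 groups, which left 20015 genes. Library sizes were scaled by TMM (factors 0.935 to 1.05), and a quasi-likelihood model with robust dispersion was fitted to all 12 libraries with 1 mean per group and 8 residual degrees of freedom. The common biological coefficient of variation was 0.143. The 5 comparisons were Dex against saline in PL, Dex against saline in IL, the difference of these effects (the interaction), PL against IL in saline mice and PL against IL in Dex mice. P-values were two-sided and adjusted over the genes tested by the Benjamini-Hochberg method (FDR), with a threshold of 0.05. Levels are CPM on the TMM-scaled library sizes, given as mean ± SD of 3 libraries. Fold changes are log2 values with their SE.

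Before the data were examined, 37 gene lists were fixed: metabolic pathways, signalling and stress responses, synaptic genes and channels, markers of brain cell types, of neighbouring brain tissue and of cortical layers, and RNA quality classes. The labels, with the 2 genes named in the series title, were in view when the lists were written. Of these lists, 36 had tested members. Each was tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 36 lists within a comparison, and again with the correlation estimated per list. A list score is the mean over the members of the log2 CPM (prior count 2) minus the gene's mean over the 12 libraries; scores of 3 against 3 libraries were compared with an exact permutation test, two-sided, whose smallest possible p is 0.1. Score differences between same-numbered libraries were added after seeing the data, with an exact sign-flip permutation test.

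Named genes followed a rule fixed at the same time. For each effect of Dex it takes Srebf1 and Phgdh, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap, with a mean of at least 1 CPM and no predicted name, and up to 4 members per list past the threshold. Where fewer than 10 genes pass, the 10 with the smallest p are named as values without a call. The interaction gives the 5 smallest p in each direction. Each region comparison gives the 8 largest changes in each direction under the same conditions and up to 4 members per list. Other list members are named with their values where their list is described. Some genes that the rule takes are not reported here.

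Whether the sample numbers pair the libraries was checked from the correlation of the libraries' deviations from their group means. It was 0.453 to 0.572 for same-numbered IL Dex and IL saline libraries (mean 0.504) and −0.00478 to 0.249 for same-numbered PL Dex and PL saline libraries (mean 0.0832). Across the regions the mean for same-numbered libraries was 0.168 in saline mice and −0.105 in Dex mice. It was 0.156 for IL Dex with PL saline and −0.0415 for IL saline with PL Dex. Means below 0 show no pairing by number there. The batch number is the only pairing that the labels offer, and a fit with it as a block was one of the alternatives. Library pairs of one group differed by a chi-square per degree of freedom of 3.64 to 13.4, so no pair agreed within sampling noise.

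Gene GC content was that of the longest transcript in the GENCODE M21 annotation of the same build (Biostrings 2.70.1), known for 19992 of the 20015 tested genes (99.89%). A GC correction was added after seeing the data: each library's deviation was fitted on GC content with a natural spline of 5 degrees of freedom, and the fitted values entered the model as offsets. GC trends were measured over 11358 genes with a mean log2 CPM above 3. The alternatives fixed at the same time as the lists were RLE size factors, no low-count filter, DESeq2 1.42.0, the batch block, each library left out in turn, a fit of only the 6 libraries compared, and genes of at least 10 CPM for the similarity of the effects. Added after seeing the data were the GC correction, alone and with the block, counts thinned to the smallest library, both PL saline libraries 1 and 2 left out, and the GC correction without PL Dex library 3.

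The fits were tested on simulated counts for the 20015 genes with 100 genes changed 1.5-fold and 100 changed 2-fold. In the PL comparison, edgeR recovered 19 and 59, with 10 false calls. In the IL comparison, it recovered 21 and 51, with 7 false calls. For PL against IL, 21 and 59 were recovered in saline (3 false calls) and 25 and 52 in Dex (10 false calls). For the interaction, 4 and 42 were recovered, with 5 false calls. On the same counts DESeq2 recovered 92 of the 200 genes in PL (18 false calls), 80 in IL (14), 86 for the regions in saline (8) and in Dex (19), and 60 for the interaction (13). A fatty acid synthesis list shifted by 0.25 on the log2 scale in simulated PL Dex libraries had an FDR of 4.45e-08 with the preset correlation and 0.0259 with an estimated one, and 2 of the 35 other lists, which were not shifted, were called with the preset correlation. Without a shift the preset FDR was 0.965 and 0 of the 35 were called. The simulated genes were drawn independently of each other. These draws therefore do not test the preset correlation on lists whose genes move together.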

Results

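PolyA RNA was sequenced from prelimbic (PL) and infralimbic (IL) prefrontal cortex of mice that had been given pairings of a tone with a foot shock and then received dexmedetomidine (Dex) or saline. The 4 groups, PL saline, PL Dex, IL saline and IL Dex, each hold 3 libraries. The total count per library was 6867249 to 8847876 in PL saline, 6853832 to 7912150 in PL Dex, 10603069 to 16530596 in IL saline and 5419187 to 10874464 in IL Dex. The IL saline levels thus rest on the deepest counts. The noncoding RNA Gm26917 took 1.92% ± 0.15 of the counts in IL saline, 1.87% ± 0.144 in IL Dex, 1.09% ± 0.458 in PL Dex and 0.823% ± 0.266 in PL saline. The first principal component held 35.8% of the variance and separated the regions. Its scores were 17.9 to 48.8 for the PL libraries and −38.4 to −29.3 for the IL libraries. The PL libraries fell into 2 sets that cross treatment. PL Dex libraries 1 and 2 and PL saline library 1 scored 22.5, 17.9 and 19.6, nearer to IL. PL Dex library 3 and PL saline libraries 2 and 3 scored 48.8, 46.9 and 48.4.

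The title of the series names Srebf1, which encodes the lipid transcription factor SREBP1, and Phgdh, which encodes the first enzyme of serine synthesis from glucose, in astrocytes of prelimbic cortex. The level of Srebf1 (ENSMUSG00000020538, GRCm38 chromosome 11, 60199089 to 60222581) was 18.9 ± 1.51 CPM in PL saline (SD, n = 3) and 32.0 ± 6.58 CPM in PL Dex, with each PL Dex library (38.5, 32.1 and 25.3 CPM) above each PL saline library (18.5, 17.6 and 20.5 CPM). In infralimbic cortex it was 45.1 ± 0.912 CPM with saline and 45.3 ± 6.77 CPM with Dex. Srebf1 overlaps Rai1 on the other strand and 2 microRNA genes on its own, and counting used no strand. In PL the log2 fold change was 0.76 (SE 0.155, 95% interval 0.436 to 1.08, a 1.69-fold difference), rank 16 of all tested genes by p, with an adjusted p of 0.108 over all genes tested in edgeR. It was past the threshold without the low-count filter (adjusted p 0.00182), in DESeq2 (0.00502) and without PL Dex library 3 (log2 fold change 0.90, adjusted p 0.00532), and it was 0.50 (SE 0.13, adjusted p 0.583) after the GC correction. Over these and the other alternatives the adjusted p ran from 0.00182 to 0.881. In IL the log2 fold change was 0.01 (SE 0.143, 95% interval −0.287 to 0.31, adjusted p 1).

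Phgdh (ENSMUSG00000053398, chromosome 3, 98313170 to 98339990, with no overlapping gene) was at 21.1 ± 0.72 CPM in PL saline and 26.4 ± 5.28 CPM in PL Dex, a log2 fold change of 0.32 (SE 0.151, 95% interval 0.00622 to 0.637, adjusted p 0.35 in edgeR). After the GC correction its log2 fold change in PL was 0.07. In IL it was at 37.7 ± 3.2 CPM with saline and 37.3 ± 4.12 CPM with Dex. Both genes were higher in IL than in PL, with log2 fold changes of PL against IL of −1.26 (SE 0.151, adjusted p 2.68e-05) for Srebf1 and −0.84 (SE 0.146, adjusted p 0.000645) for Phgdh in saline mice. In Dex mice the values were −0.51 for both (SE 0.148 and 0.147, adjusted p 0.0405 and 0.0387). The calls in Dex mice were lost for Srebf1 without IL Dex library 1 (0.116) or 3 (0.168) or PL Dex library 2 (0.0664) or 3 (0.158), and for Phgdh without IL Dex library 2 (0.0959) or 3 (0.17) or PL Dex library 2 (0.0607) or 3 (0.15). After the GC correction the region values of Srebf1 and Phgdh were −0.912 and −0.514 in saline mice and −0.442 and −0.453 in Dex mice. All stayed past the threshold (adjusted p 7.42e-05, 0.00747, 0.0255 and 0.022 in edgeR). The genes are the study's own choice on these samples, so their values here are not independent evidence.

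**Figure D1:**
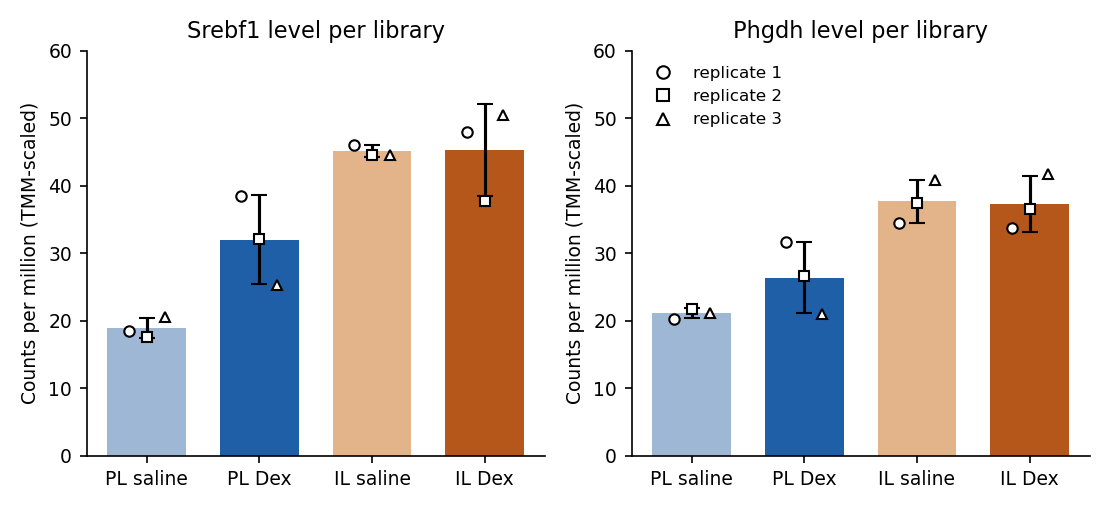
Levels of Srebf1 and Phgdh in TMM-scaled CPM in the 4 groups; bars are means, error bars the SD of 3 libraries, and points the single libraries, shaped by replicate number. Mean Srebf1 was 18.9 CPM in PL saline, 32.0 in PL Dex, 45.1 in IL saline and 45.3 in IL Dex; mean Phgdh was 21.1, 26.4, 37.7 and 37.3 CPM.

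The first comparison asks what Dex changed in prelimbic cortex. Genes of fatty acid synthesis regulated by SREBP1 were higher with Dex than with saline, with a positive log2 fold change in 19 of 22 measured members and a median of 0.22. Immediate early genes, which neuronal activity induces within minutes, were also higher (26 of 37 positive, median 0.18), as were genes of glucose uptake, glycogen and lactate (24 of 30 positive, median 0.18). Genes of cytosolic ribosomal proteins were lower (13 of 80 positive, median −0.18), and so were nuclear genes for subunits of oxidative phosphorylation (22 of 78 positive, median −0.13). These 5 lists passed the test with the preset correlation (camera adjusted p, in the same order, 0.00106, 0.00827, 0.00827, 0.00106 and 0.0328). None passed with an estimated one (adjusted p = 0.0691, 0.867, 0.867, 0.867 and 0.885 with an estimated correlation).

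Of the 22 fatty acid synthesis genes, none passed over all genes tested (edgeR, 0 higher and 0 lower); adjusted over the list alone, 3 rose and 1 fell. Those that rose were Srebf1, Acacb, an acetyl-CoA carboxylase (7.85 ± 3.13 against 4.17 ± 0.789 CPM, log2 fold change 0.90, SE 0.301), and Fasn, the fatty acid synthase (360 ± 50.6 against 279 ± 41.1 CPM, 0.36, SE 0.125). The fatty acid elongase gene Elovl6 fell (−0.34, SE 0.117). Among those not called were the citrate carrier Slc25a1 (0.44), the phosphatidate phosphatase Lpin1 (0.33), Acss2 (0.29) and Gpam (0.24). The list was written with Srebf1 in view from the title and is therefore no independent evidence of direction. Without Srebf1 it had 18 of 21 positive members, a median of 0.20 and an adjusted p of 0.00635 (adjusted p = 0.16 with an estimated correlation). The list score was 0.0794 ± 0.0463 in PL Dex and −0.158 ± 0.0505 in PL saline, a difference with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. The list passed the preset test without each PL library in turn and after the GC correction (adjusted p 0.00898, adjusted p = 0.215 with an estimated correlation), in which the median was 0.11.

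**Figure D2:**
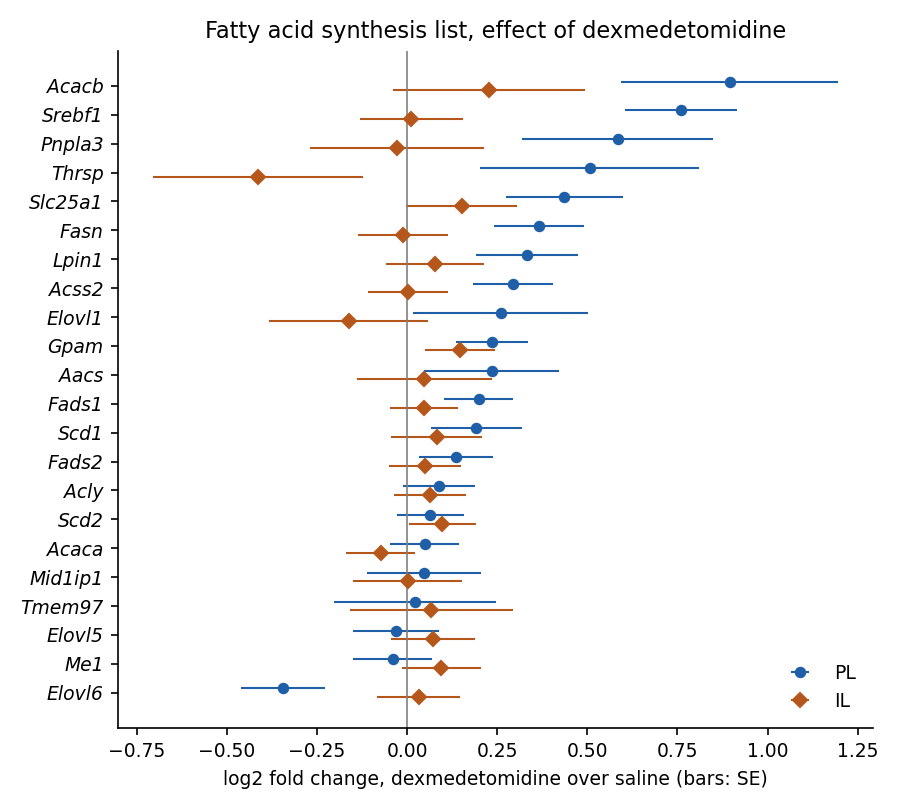
Log2 fold change of Dex against saline for the 22 measured genes of the fatty acid synthesis list, in prelimbic and in infralimbic cortex; points are edgeR estimates from 3 against 3 libraries and error bars their SE. In PL 19 of 22 values lie above 0 (median 0.22), and in IL 17 of 22 (median 0.05).

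Among the immediate early genes, adjusted over the list alone, 6 rose and 1 fell, and over all genes tested edgeR called 0. The 6 were Btg2 (34.8 ± 8.41 against 20.8 ± 2.72 CPM, log2 fold change 0.75, SE 0.164), Fos (36.2 ± 5.29 against 23.8 ± 1.14 CPM, 0.61, SE 0.14), Egr2 (0.62), Jun (0.55), Dusp1 (0.52) and Fosb (0.41). Atf3 fell, at 0.236 against 1.34 CPM. The glucose list had 0 members past the threshold even over the list alone; the pyruvate kinase gene Pkm had a log2 fold change of 0.25 and the glucose transporter Slc2a1 of 0.32. The list test for immediate early genes was lost without PL Dex library 3 (adjusted p 0.382) or PL saline library 1 (0.101), and that for glucose genes without PL saline library 1 (0.222). Without both PL saline libraries 1 and 2 these 2 lists were lost as well (0.961 and 0.688). After the GC correction the adjusted p was 0.0772 for immediate early genes, 0.618 for glucose genes, 9.09e-11 for ribosomal genes and 9.31e-06 for oxidative phosphorylation genes (adjusted p = 0.975 with an estimated correlation for each). Ribosomal protein genes lost the call without PL Dex library 1 (0.063), PL Dex library 2 (0.437) or PL saline library 3 (0.197). Oxidative phosphorylation genes lost it without PL Dex library 1 (0.347) or 2 (0.967) or PL saline library 2 (0.0867) or 3 (0.681). The scores of the ribosomal list were −0.246, −0.362 and 0.214 in PL Dex libraries 1 to 3 and −0.131, 0.0982 and 0.174 in PL saline libraries 1 to 3. Between same-numbered libraries, the Dex minus saline score was positive in 3 of 3 pairs for fatty acid synthesis, immediate early and glucose genes. The exact sign-flip permutation p was 0.25 for each, the smallest that 3 pairs allow. For fatty acid and glucose genes all PL Dex scores lay above all PL saline scores, so any pairing would give 3 of 3. The numbers also showed little pairing in PL. The score differences went both ways for ribosomal (−0.115, −0.46 and 0.04) and oxidative phosphorylation genes (−0.066, −0.448 and 0.092). With the batch number as a block, 2 further lists passed, glucocorticoid-responsive genes (adjusted p 0.0261, 0.151 without the block, adjusted p = 0.867 with an estimated correlation) and markers of mural cells and meningeal fibroblasts (0.0137, 0.0706 without the block, adjusted p = 0.867 with an estimated correlation). Their scores went both ways within the batch pairs, by 0.352, 0.455 and −0.289 for the glucocorticoid list and 0.675, −0.257 and 0.654 for the mural list (exact sign-flip permutation p 0.5 for each).

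The test of single genes called 4 transcripts in PL, all lower with Dex: Zfp942, Gm25107, Gm37602 and Gm37895, each with an adjusted p of 0.0497. Zfp942, a zinc finger gene on chromosome 17 (21926960 to 21962464), was at 24.2 ± 5.71 CPM with Dex and 44.4 ± 2.47 CPM with saline (log2 fold change −0.87, SE 0.149). Gm25107, annotated as a small nucleolar RNA inside Lrch2 on chromosome X (147484293 to 147484421), was at 7.28 ± 2.66 and 19.4 ± 2.58 CPM (−1.41, SE 0.224). Gm37602 (chromosome 1, 25804097 to 25807406; 25.3 ± 2.2 against 46.8 ± 7.81 CPM) and Gm37895 (25775757 to 25780306; 44.4 ± 4.11 against 73.3 ± 8.87 CPM) are transcripts annotated as awaiting experimental evidence. Both lie inside Adgrb3 on its own strand, so their counts can hold reads of Adgrb3 and stay uncertain. At an unadjusted p under 0.05, 2784 genes (13.9%) differed, 1396 higher and 1388 lower, and 2881 genes (14.4%) had groups that did not overlap, where chance gives 10%. DESeq2 called 123 genes, 48 higher and 75 lower.

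Of the 6 further genes among the 10 smallest p, edgeR called none, whereas DESeq2 (adjusted p 0.000538 to 0.00269) and edgeR without the low-count filter (0.000197 to 0.00387) called all 6. Nr1d2, a repressor in the circadian clock (chromosome 14, 18204054 to 18239127), was at 115 ± 13.3 CPM with Dex and 170 ± 9.55 CPM with saline (log2 fold change −0.56, SE 0.103, adjusted p 0.0734). The adaptor gene Sh2d3c was at 21.8 ± 1.34 and 10.4 ± 2.58 CPM (1.08, SE 0.204, adjusted p 0.0774, and 0.0438 with the batch block), and the dynein gene Dnah17 at 9.96 ± 2.58 and 4.25 ± 0.388 CPM (1.22, SE 0.233, adjusted p 0.0774). Gm37051 (−1.12) and Gm37011 (−1.03) also lie inside Adgrb3, and Gm47472 (−0.70) lies inside Syt1 on the other strand. With the batch block Zfp942 and Gm37895 were no longer called (adjusted p 0.0619 for both). The number of called genes was 0 without PL Dex library 1, PL Dex library 2 or PL saline library 2, 2 without PL saline library 1, 8 without PL saline library 3 and 1528 without PL Dex library 3 (576 higher, 952 lower, the 4 among them). Zfp942 had an adjusted p of 0.332 without PL Dex library 1, 0.132 without PL Dex library 2, and 0.159, 0.317 and 0.0506 without PL saline libraries 1, 2 and 3. The other 3 called transcripts were each lost without PL Dex library 1 or 2 or PL saline library 1 or 2, with an adjusted p of 0.0505 to 0.322 for Gm25107, 0.132 to 0.332 for Gm37602 and 0.0874 to 0.332 for Gm37895. Without PL Dex library 3, Nr1d2 (0.00345), Dnah17 (0.00561), Gm37051 (0.0071), Gm47472 (0.00747), Gm37011 (0.0101) and Sh2d3c (0.0106) were past the threshold. Gm37051 was past it without PL saline library 3 too (0.0347). With the GC correction and without PL Dex library 3, only Nr1d2 (edgeR adjusted p 0.0395) and Dnah17 (0.0443) of these genes were past it. Gm37051, Gm47472, Gm37011 and Sh2d3c were then not called. Of the called transcripts, Zfp942 (0.0556), Gm37602 (0.24) and Gm37895 (0.277) lost the call in that fit.

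Levels in PL moved with the GC content of the genes. The Spearman coefficient between GC content and log2 fold change was 0.728 across 11358 genes, which are not independent replicates, and the median log2 fold change went from −0.29 in the bin of 38.7% GC to 0.28 in the bin of 59.4% GC. In IL the coefficient was −0.0723. The slope of library level on GC, in log2 units per 10% GC, was −0.263, −0.338 and −0.087 in PL saline libraries 1 to 3 and 0.126, 0.117 and −0.104 in PL Dex libraries 1 to 3 (exact permutation p 0.2 for the groups, smallest possible 0.1). After the GC correction 1 gene was called in PL (0 higher, 1 lower), Dbp, a clock output gene that was named after its values were seen (log2 fold change −1.03, adjusted p 0.0429), and 1188 genes had an unadjusted p under 0.05. The 4 called transcripts were not among the calls, with log2 fold changes of −0.56 for Zfp942 (adjusted p 0.563), −1.25 for Gm25107 (0.0867), −0.37 for Gm37602 (0.736) and −0.38 for Gm37895 (0.69).

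**Figure D3:**
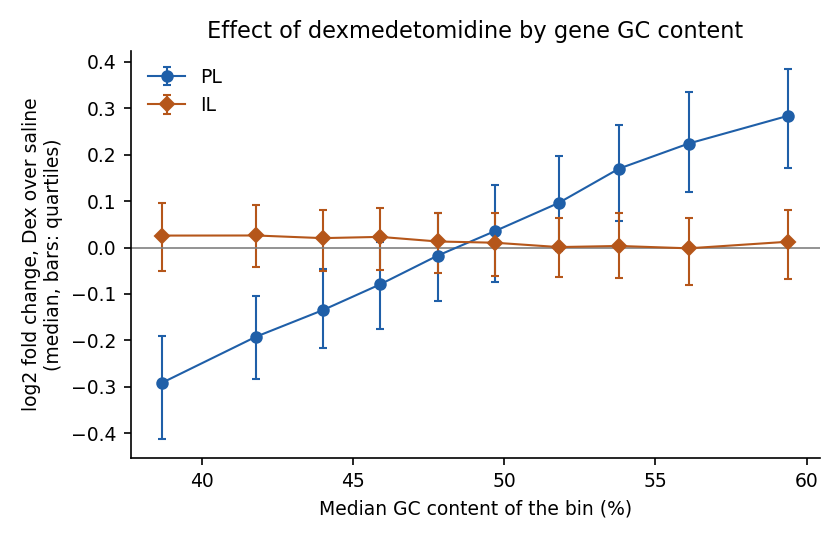
Median log2 fold change of Dex against saline (points) with quartiles (bars) in 10 bins of gene GC content in percent, for prelimbic and infralimbic cortex. In PL the medians go from −0.29 to 0.28 across the bins, and in IL they are 0.03 in the lowest bin and 0.01 in the highest.

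The second comparison asks the same in infralimbic cortex. Immediate early genes were higher with Dex in IL as well, with 30 of 37 members positive and a median log2 fold change of 0.12. Genes of potassium and HCN channels, which set neuronal excitability, were higher (19 of 21 positive, median 0.12), as were GABA receptor and synthesis genes (14 of 18, median 0.08) and blood cell markers (5 of 6, median 0.52). The adjusted p with the preset correlation was 0.00127, 0.00524, 0.0383 and 0.0164 (adjusted p = 0.618 with an estimated correlation for each). No member of these lists was called by edgeR over all genes or over the list alone; Egr2 had a log2 fold change of 0.34, Dusp1 of 0.28, Hcn4 of 0.42 and the globin gene Hba-a1 of 0.97. The fatty acid synthesis list had 17 of 22 positive members with a median of 0.05 and an adjusted p of 0.313.

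EdgeR called 0 genes for Dex in IL, with 213 genes (61 higher, 152 lower) at an unadjusted p under 0.05, and DESeq2 called 0. Without the low-count filter edgeR called 3, among them the small structural RNA Rn7s6 (−2.98, adjusted p 7.9e-08). The groups did not overlap for 1557 genes (7.78%), where chance gives 10% for libraries that are not paired. The 10 smallest p, all with an adjusted p of 1, included small structural RNAs (Rn7s6 −2.97, Gm22317 −3.52, Gm24616 −1.59 and Gm25179 −1.28), and the splicing factor gene Hnrnpf (28.0 ± 3.91 against 19.9 ± 1.7 CPM, log2 fold change 0.48), Arhgap24 (8.2 ± 0.479 against 4.91 ± 1.14 CPM, 0.73), Mipol1 (−0.79), Fam50a (−0.55), Lrrc47 (−0.45) and 4930589P08Rik (−1.72). Between same-numbered libraries, whose deviations went together in IL, the score of Dex minus saline was 0.0981, 0.0976 and 0.095 for immediate early genes, 0.101, 0.103 and 0.0811 for channels, 0.101, 0.0569 and 0.0554 for GABA genes and 0.246, 0.668 and 0.263 for blood markers (exact sign-flip permutation p 0.25 for each, the smallest that 3 pairs allow). With the batch block the adjusted p of these lists was 0.00019, 0.00226, 0.0358 and 0.00744. Leaving out single libraries breaks a pair. The immediate early list was then lost without IL Dex library 3 (adjusted p 0.437) or IL saline library 1 (0.257), and the channel list without IL Dex library 3 (0.437) or IL saline library 1 (0.101) or 2 (0.134). The blood list was lost without IL Dex library 2 (0.165) or 3 (0.0775) or IL saline library 1 (0.101), and the GABA list without IL Dex library 1 (0.0624), 2 (0.0591) or 3 (0.258) or IL saline library 1 (0.237). The number of called lists was 4, but 0 without IL Dex library 3 or IL saline library 1, 9 without IL Dex library 1 and 11 without IL saline library 3.

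The third comparison asks whether the effect of Dex differed between the regions. The effect on ribosomal protein genes was lower in PL than in IL (12 of 80 members with a positive difference, median −0.22), with 13 of 80 positive in PL and 55 of 80 in IL. The same held for oxidative phosphorylation genes (20 of 78, median −0.15) and for GABA receptor and synthesis genes (4 of 18, median −0.21; 5 of 18 positive in PL and 14 of 18 in IL). Fatty acid synthesis genes had the higher effect in PL (17 of 22, median 0.14). The adjusted p of the 4 lists with the preset correlation was 0.000307, 0.047, 0.0158 and 0.0427 (adjusted p = 0.971, 0.971, 0.971 and 0.45 with an estimated correlation). After the GC correction it was 1.31e-10, 1e-04, 0.0407 and 0.299 (adjusted p = 0.972 with an estimated correlation for each). Without Srebf1 the fatty acid list had 16 of 21 members with a positive difference and a median of 0.12. It then lost the call (camera adjusted p 0.116, adjusted p = 0.971 with an estimated correlation). For Srebf1 the difference of the log2 fold changes was 0.75 (SE 0.211, 95% interval 0.308 to 1.19, adjusted p 0.716) and for Phgdh 0.33 (95% interval −0.1 to 0.762, adjusted p 0.725). After the GC correction these differences were 0.47 (SE 0.176) for Srebf1 and 0.0603 (SE 0.174) for Phgdh.

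EdgeR called 0 genes for this difference, with 1347 at an unadjusted p under 0.05, and DESeq2 called 0; without the low-count filter edgeR called 4 and without PL Dex library 3 it called 169 (39 higher, 130 lower), among them Srebf1 (0.89, adjusted p 0.0403). The genes with the smallest p, all with an adjusted p of 0.716, were Lrrc47 (1.01), Smg9 (0.81), the receptor Notch1 (0.70), the ciliary rootlet gene Crocc (0.95) and the chloride channel Ano1 (1.55) with a higher effect in PL, and Zfp942 (−0.87), its neighbour Zfp943 (−0.89), Gm37602 (−0.82), Arl5b (−0.59) and Calcrl (−1.14) with a lower one. Without PL Dex library 3, Crocc (adjusted p 0.0219), Zfp943 (0.0264), Zfp942 (0.03), Notch1 (0.0393), Lrrc47 (0.0403), Arl5b (0.0403) and Smg9 (0.0431) were past the threshold. Crocc (0.0118) and Lrrc47 (0.0169) were past it without the low-count filter too. With the GC correction and without PL Dex library 3, 0 of these 10 genes were called. The fatty acid list lost its call without IL Dex library 1 (0.0684) or 2 (0.0698), PL Dex library 1 (0.0606) or 3 (0.0605), IL saline library 1 (0.0636) or PL saline library 1 (0.0565). The GABA list lost it without PL Dex library 2 (0.151) or IL saline library 1 (0.0636). The ribosomal list lost it without IL Dex library 2 (0.0809), PL Dex library 2 (0.186), IL saline library 1 (0.0636) or PL saline library 3 (0.0574). The oxidative phosphorylation list lost it without IL Dex library 2 (0.206) or 3 (0.532), PL Dex library 1 (0.468) or 2 (0.864), IL saline library 1 (0.704), or PL saline library 2 (0.0882) or 3 (0.81). Across the 20015 genes the effects of Dex in PL and IL had a Pearson correlation of 0.0537 (Spearman −0.00406, same sign in 48.8%), and 0.0114 over the 10575 genes of at least 10 CPM.

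The fourth comparison asks how the regions differ in saline mice. Markers of excitatory neurons were higher in prelimbic than in infralimbic libraries, with 6 of 12 called higher, 0 lower and a median log2 fold change of 0.49. Markers of striatal neurons were lower (11 of 17 called lower, median −1.92), and so were markers of septum and olfactory areas (9 of 14, median −1.49) and of choroid plexus and ependyma (5 of 10, median −1.52, the same with genes at 0 set to their bound). The adjusted p of the 4 lists was 3.54e-08, 1.48e-10, 1.48e-10 and 5.65e-05 with the preset correlation (adjusted p = 0.326, 0.436, 0.326 and 0.326 with an estimated correlation). The striatal score was 0.0941, −1.92 and −1.46 in PL saline libraries 1 to 3 and 1.11, 1.23 and 0.869 in IL saline libraries 1 to 3 (difference −2.17, exact permutation p 0.1, the smallest possible).

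Of the excitatory markers, the transcription factor gene Neurod6 was at 108 ± 4.17 CPM in PL and 25.6 ± 0.775 CPM in IL (log2 fold change 2.07, SE 0.163, adjusted p 9.9e-07). Tbr1 had a log2 fold change of 0.96 and Sv2b of 0.81. Of the striatal markers, Ppp1r1b, which encodes the dopamine-regulated phosphatase inhibitor DARPP-32, was at 42.8 ± 20.9 CPM in PL and 179 ± 22.7 CPM in IL (−2.08, SE 0.376, adjusted p 0.00594), the adenylyl cyclase Adcy5 had a value of −1.51 and Rxrg of −1.52. Of the septal and olfactory markers, Sp8 (−2.37), Prokr2 (−2.41), Zic4 (−2.49) and Trpc4 (−0.94) were lower in PL. Deep-layer cortical markers were higher (7 of 16 called higher, 1 lower, median 0.35, list adjusted p 0.0118, adjusted p = 0.326 with an estimated correlation), among them Fezf2 (1.22) and Rprm (1.19), with Bcl11b, which striatal neurons also express, lower (−0.67). This list was not past the threshold without PL saline library 1 (0.143) or without libraries 1 and 2 both (0.111).

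Beside these markers, 5 further lists differed. Cholesterol synthesis and uptake genes were higher in PL, with 11 of 27 called higher and 3 lower (median 0.20, adjusted p 0.00815, adjusted p = 0.451 with an estimated correlation); Hmgcs1 was at 333 ± 30.2 against 174 ± 5.25 CPM (0.94, SE 0.119). Endoplasmic reticulum chaperones were higher (8 of 18, 0 lower, median 0.31, adjusted p 0.0015, adjusted p = 0.451 with an estimated correlation), among them Atf6 (0.50), Pdia3 (0.57) and Dnajb9 (0.69). GABA receptor and synthesis genes were higher (9 of 18, 3 lower, median 0.30, adjusted p 0.00815, adjusted p = 0.451 with an estimated correlation), with Gabra3 at 0.91 and Gabbr2 at 0.72. Potassium and HCN channels were higher (8 of 21, 1 lower, median 0.31, adjusted p 0.0119, adjusted p = 0.647 with an estimated correlation, and adjusted p 0.0877 without PL saline library 3), with Kcnc2 at 0.93. Astrocyte markers were lower (5 of 22, 1 higher, median −0.23, adjusted p 0.0368, adjusted p = 0.712 with an estimated correlation); Gfap was at 43.4 ± 7.81 against 86.9 ± 5.47 CPM. The astrocyte call was lost without IL saline library 2 (0.184) or PL saline library 3 (0.0862) and after the GC correction (0.0711). With the batch block the glucocorticoid-responsive list passed too (0.0439, 0.0934 without the block, adjusted p = 0.858 with an estimated correlation). The serine list had 1 member higher and 4 lower of 18 (adjusted p 0.116).

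In all, edgeR called 3737 genes between the regions in saline mice, 1996 higher and 1741 lower in PL, with 6525 at an unadjusted p under 0.05 and 8067 (40.3%) whose groups did not overlap, where chance gives 10%. The largest differences higher in PL were in Rxfp2 (3.08), H60b (2.86), Trbc2 (2.37), Dmrt2 (2.34), Hkdc1 (2.19, SE 0.26; 18.8 ± 4.66 against 4.15 ± 1.25 CPM), Fap (2.14), Krt80 (2.13) and Neurod6. The ciliary genes Ccdc153, Ccdc180, Crocc2, Ccdc170 and Tmem212 had 0 counts in the 3 PL saline libraries and 3.83 ± 0.739, 3.13 ± 1.2, 2.67 ± 1.22, 2.49 ± 0.684 and 2.34 ± 0.387 CPM in IL. Against a floor of 3 counts over the group (0.128 CPM), which covers counting error only, they were at least 29.9-fold, 24.4-fold, 20.8-fold, 19.4-fold and 18.3-fold lower in PL. Wdr49 had 2 counts in PL saline (0.0909 against 3.47 ± 1.52 CPM), the incretin receptor gene Glp1r was at 1.74 ± 1.27 against 27.8 ± 11.4 CPM (−4.06, SE 0.45), and the dynein gene Dnah11 at 0.653 ± 0.458 against 10.9 ± 7.31 CPM (−3.98, SE 0.949, adjusted p 0.0183, and 0.0515 and 0.0656 without PL saline libraries 2 and 3). The count was 2391, 2152 and 2437 without IL saline libraries 1, 2 and 3, and 1874 without PL saline library 2. The log2 fold changes had a Spearman coefficient of −0.564 with GC content across genes, and after the GC correction 2864 genes were called, 1809 higher and 1055 lower, of which 2141 were among the 3737.

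**Figure D4:**
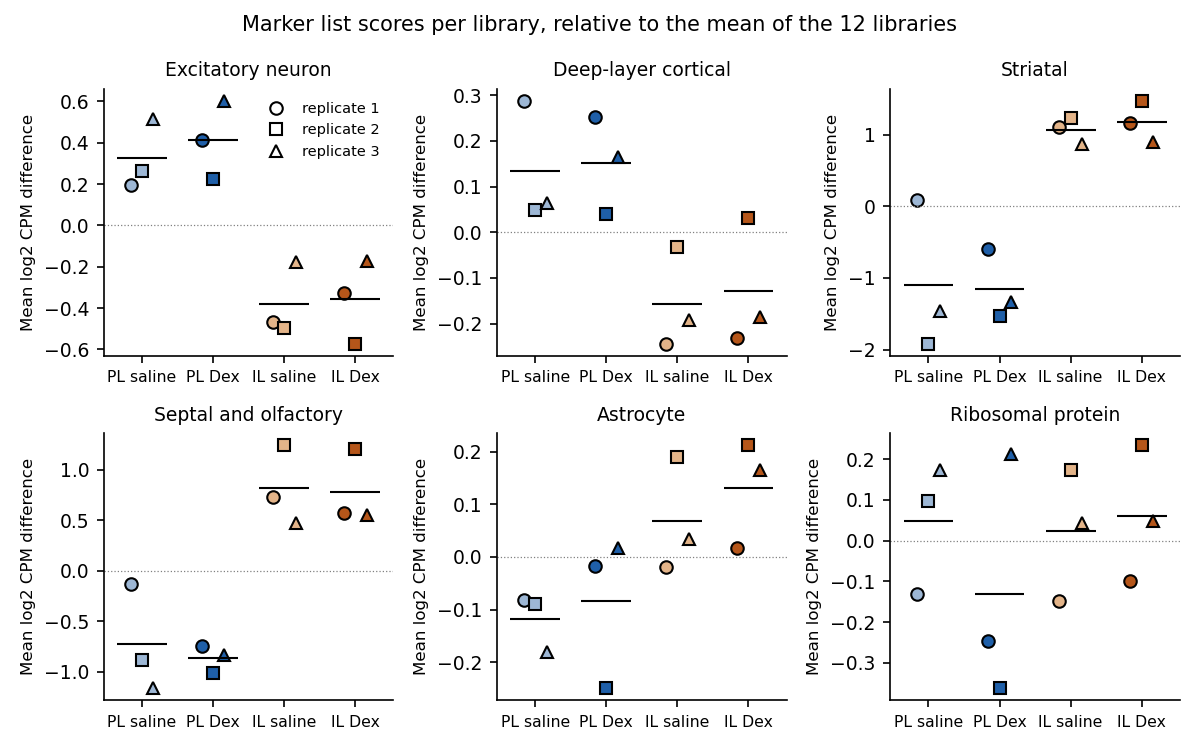
Scores of 6 gene lists in each of the 12 libraries, as the mean over list members of log2 CPM minus the gene's mean over all libraries; points are libraries, shaped by replicate number, and lines group means. The striatal score of the PL libraries lies between −1.92 and 0.0941 and that of the IL libraries between 0.869 and 1.47.

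The fifth comparison sets the regions against each other in Dex mice. Markers of excitatory neurons were again higher in PL (7 of 12 called higher, 0 lower, median 0.71), with Neurod6 at 81.1 ± 24.6 against 25.2 ± 3.96 CPM and Nptx1 at 482 ± 5.27 against 272 ± 37.8 CPM. Striatal markers (11 of 17 called lower, median −2.12), septal and olfactory markers (8 of 14, median −1.81) and choroid plexus and ependymal markers (4 of 10, median −1.84) were lower. The adjusted p was 1.2e-14, 4.88e-20, 1.8e-17 and 3.57e-05 with the preset correlation (adjusted p = 0.116, 0.157, 0.116 and 0.116 with an estimated correlation). Inhibitory neuron markers were lower (7 of 14, 1 higher, median −0.58, adjusted p 0.000875, adjusted p = 0.162 with an estimated correlation), with Gad1, which makes GABA, at 223 ± 18.3 against 424 ± 103 CPM. Deep-layer markers were higher (5 of 16, 2 lower, median 0.41, adjusted p 0.00313, adjusted p = 0.162 with an estimated correlation), with Fezf2 at 1.46 and Bcl11b at −0.91.

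Cholesterol genes were higher in PL in Dex mice too (6 of 27, 1 lower, median 0.24, adjusted p 0.000102, adjusted p = 0.162 with an estimated correlation), with Hmgcs1 at 0.58. Glucose genes were higher (4 of 30, 0 lower, median 0.20, adjusted p 0.000402, adjusted p = 0.489 with an estimated correlation), with the hexokinase Hk1 at 371 ± 12.4 against 259 ± 35.4 CPM. Endoplasmic reticulum chaperones (2 of 18, 0 lower, median 0.21, adjusted p 0.00134, adjusted p = 0.489 with an estimated correlation) and potassium and HCN channels (3 of 21, 1 lower, median 0.20, adjusted p 0.0211, adjusted p = 0.677 with an estimated correlation) were higher, with Atf6 at 0.46 and Kcnj9 at 0.80. Astrocyte markers were lower (4 of 22, 0 higher, median −0.18, adjusted p 0.00462, adjusted p = 0.648 with an estimated correlation), with Slc4a4 at −0.81. Ribosomal protein genes were lower as a list (1 of 80 called, median −0.18, adjusted p 0.000911, adjusted p = 0.726 with an estimated correlation). Blood cell markers were lower (0 of 6 called over all genes tested in edgeR and 3 adjusted over the list alone, Hba-a1 at −1.39, Hba-a2 and Hbb-bs, median −0.98, adjusted p 0.00683, adjusted p = 0.162 with an estimated correlation). Without PL Dex library 2 the calls were lost for inhibitory (0.0697), ribosomal (0.331), astrocyte (0.204) and blood (0.0628) lists. The ribosomal call was also lost without IL Dex library 2 (0.106), and the channel call without IL Dex library 1 (0.0777) or 2 (0.0745) or PL Dex library 3 (0.14).

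EdgeR called 1469 genes between the regions in Dex mice, 761 higher and 708 lower in PL, with 3962 at an unadjusted p under 0.05 and 4317 (21.6%) whose groups did not overlap, where chance gives 10%. After the GC correction it called 2025, 1264 higher and 761 lower, of which 1454 were among the 1469. The largest differences higher in PL were in Mylk3 (2.65), Hkdc1 (2.65, SE 0.282; 24.0 ± 1.73 against 4.03 ± 1.81 CPM), Krt80 (2.62), CT025671.1 (2.58), Trbc2 (2.56), Cd6 (2.48), Myl4 (2.29) and Col28a1 (2.28). Those lower in PL included Tmem212 with 1 count in the 3 PL Dex libraries (0.0453 against 2.26 ± 0.414 CPM), the neuropeptide gene Nts with 3 counts (0.139 against 5.28 ± 1.91 CPM) and Tfap2d with 3 counts (0.136 against 4.81 ± 2.68 CPM). Ndst4 was at 2.18 ± 0.236 against 108 ± 63.4 CPM (−5.64, SE 1.33, adjusted p 0.0402), and was lost with the batch block and without any single one of the 6 libraries (adjusted p 0.0546 to 0.124). The forebrain gene Six3 (−4.74), its antisense partner Six3os1 (−4.38), which cannot be told apart from it where they overlap, and Clic6 (−4.28) were likewise lost without any single one of the 6 (0.0728 to 0.133, 0.055 to 0.126 and 0.0606 to 0.127). Dnah11 (−4.24) was lost without PL Dex library 1 (0.11), 2 (0.0541) or 3 (0.138), CT025671.1 without PL Dex library 1 (0.056), and Col28a1 without IL Dex library 1 (0.0965) or 3 (0.206) or PL Dex library 1 (0.15) or 3 (0.0642). The count was 793 without IL Dex library 2. Of the genes called in both states, 587 were higher in PL in both (75.9 if the calls were independent) and 518 lower (61.6), and the region effects in saline and Dex mice, which share no library, had a correlation of 0.662 across genes (Spearman 0.556).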

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

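The differences of effect between the regions were tested as designed, as were the trend among long noncoding genes and the lists over other splits of the samples; the remaining tests here (libraries of one group, GC slopes, GC-corrected values, neighbouring tissue, astrocyte share and genes over other splits) were chosen only after the result was seen.

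Of the 36 gene lists, 4 stood out because the effect of Dex differed between prelimbic and infralimbic cortex in a test of the difference itself. Fatty acid synthesis genes had a median difference of 0.14 with an adjusted p of 0.0427 (adjusted p = 0.45 with an estimated correlation), lost after the GC correction (0.299), without both PL saline libraries 1 and 2 (0.163) and without IL Dex library 1 or 2, PL Dex library 1 or 3, IL saline library 1 or PL saline library 1 (0.0565 to 0.0698). With Srebf1 taken out of the list its call was lost as well (camera adjusted p 0.116, adjusted p = 0.971 with an estimated correlation). GABA receptor and synthesis genes had −0.21 with 0.0158 (adjusted p = 0.971 with an estimated correlation), lost without PL Dex library 2 (0.151) or IL saline library 1 (0.0636). Ribosomal protein genes had −0.22 with 0.000307 (adjusted p = 0.971 with an estimated correlation), lost without IL Dex library 2, PL Dex library 2, IL saline library 1 or PL saline library 3 (0.0574 to 0.186). Oxidative phosphorylation genes had −0.15 with 0.047 (adjusted p = 0.971 with an estimated correlation), lost without IL Dex library 2 or 3, PL Dex library 1 or 2, IL saline library 1, or PL saline library 2 or 3 (0.0882 to 0.864). Of 60 splits drawn from the 200 possible, which include the real one, 8, 12, 40 and 38 called these lists. The number of called lists was 4, and 54 of the 60 splits called as many (highest other 17), as did 8 of the 10 among them that part every same-numbered pair within each region (highest other 8), so chance is not excluded.

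The change of PL levels with GC content had a Spearman coefficient of 0.728 over 11358 genes, and GC content accounted for 47.7% of the variance of their log2 fold changes. Libraries of one group differed with GC content too, by an absolute coefficient of up to 0.58 (PL saline libraries 2 and 3), and the trend held for 314 long noncoding genes (0.564) beside 10487 protein-coding genes (0.732). A GC bias between libraries is thus a candidate explanation; simulated PL counts with the trend and no other effect gave 2287 genes at an unadjusted p under 0.05, against 2784 observed, and edgeR called 0 of them. A rise of GC-rich genes under Dex stays open, since the slopes gave an exact permutation p of 0.2 and 3 against 3 libraries cannot go under 0.1.

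Markers of striatum, septum and olfactory areas were higher in IL than in PL libraries. The tables argue against GC content as the cause, as the striatal median in saline mice was −1.7 after the correction and −1.92 before it (list adjusted p 2.82e-11 after it, adjusted p = 0.294 with an estimated correlation). Between libraries of one group the striatal markers moved together (residual correlation 0.655), with a score of 0.0941 in PL saline library 1 against −1.92 and −1.46 in libraries 2 and 3, which is what a varying share of neighbouring tissue in the dissected samples could give. Of the 17 striatal markers, 16 were at 1 CPM or more in PL saline and 2 belong to another list too; the most abundant, Pde10a and Adcy5, were at 256 and 193 CPM in PL saline and 621 and 550 CPM in IL saline. A difference between the regions themselves stays open as untested.

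Srebf1 and the fatty acid synthesis genes were higher in PL Dex than in PL saline libraries (log2 fold change 0.76, list median 0.22). Part of both values went with GC content. After the correction Srebf1 was at 0.498 (SE 0.13, adjusted p 0.583). The list then had a median of 0.11 and an adjusted p of 0.00898 (adjusted p = 0.215 with an estimated correlation). What remained does not decide whether GC content was the whole cause. Srebf1 did not pass over all genes tested, and the list passed with the preset correlation only. Infralimbic or striatal tissue stays undecided for Srebf1. The share needed (50%) would raise the striatal median by 1.24 where it was −0.194 (SD 0.728 over 17 members). These members move together, so the spread between libraries is what counts. The striatal score was −1.15 ± 0.497 in PL Dex and −1.1 ± 1.05 in PL saline (exact permutation p 0.9). PL saline library 1 lay far above the other PL saline libraries, and the median of −0.194 rests partly on it. For the list even libraries of IL tissue alone would give a median of 0.16, against 0.22 observed. A higher astrocyte share is argued against for Srebf1. The median of 22 astrocyte markers was 0.0224 (SD 0.226), although Gfap and Fgfr3 among them rose. The library score of the markers was −0.0834 ± 0.145 in PL Dex and −0.117 ± 0.0554 in PL saline, a difference of 0.0334. For the list, whose median lies within the spread of the markers, a higher astrocyte share cannot be told apart from a change within cells. An effect of Dex on these genes stays a hypothesis, found and tested on the same libraries. The list was called by the real split alone of 10 (smallest other adjusted p 0.0824), too few splits for a share under 0.05. The other lists called for Dex in PL were also called by splits that mix the treatments. Of the 10 splits, 3 called immediate early genes, 4 glucose genes, 8 ribosomal genes and 8 oxidative phosphorylation genes. An adjusted p as small as the real one came in 3, 2, 7 and 8 of them.

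The 6 libraries of a comparison make 10 splits, the real one included, which cannot give a share under 0.05. For Dex in PL, where edgeR called 4 genes, 2 of 10 splits called as many. The highest other count was 116. In that split PL Dex 1, PL Dex 2 and PL saline 1 stood against PL Dex 3, PL saline 2 and PL saline 3. The same division shows on the first principal component, which separated the regions. The scores there, in the same order, were 22.5, 17.9 and 19.6, nearer to IL, against 48.8, 46.9 and 48.4. The split also sets PL Dex libraries 1 and 2 against PL saline libraries 2 and 3, and so holds part of the drug contrast. Its count therefore cannot be laid to the drug or to this structure of the samples alone. Both libraries numbered 1 stood against both numbered 3, but those numbered 2 were parted. With the batch number as a block the real split called 3 genes. As many genes at an unadjusted p under 0.05 as in the real split (2784) were found in 3 of 10 splits (highest other 3408), and in 2 of the 4 that part every same-numbered pair. For Dex in IL all 10 splits reached the real count of 0, as any split must (highest other 0; 213 genes at an unadjusted p under 0.05, and 0 in DESeq2). For the regions 1 of 10 splits reached 3737 genes in saline mice and 1 of 10 reached 1469 in Dex mice, with 0 as the highest other in each. For the difference of the Dex effects all 60 splits drawn reached the real count of 0, as any split must, so this count says nothing about chance; the highest called 56. There 1347 genes had an unadjusted p under 0.05, a number that 17 of the 60 splits reached (highest other 2906), and DESeq2 called 0. As many lists as the real split were called by 9 of 10 splits for Dex in PL (real 5, highest other 13), 7 of 10 for Dex in IL (4 and 12), 3 of 10 for the regions in saline mice (10 and 18) and 2 of 10 in Dex mice (13 and 16). Of the 10 splits, 4 part every same-numbered pair as the real one does, again too few for a share under 0.05, and the other 6 put a pair into each group, so that what a pair shares adds to the difference. Among the 4, as many lists were called by 3 splits for Dex in PL (highest other 7) and by the real split alone for Dex in IL (highest other 0), for the regions in saline mice (6) and in Dex mice (8). For Dex in IL, where same-numbered libraries deviated together, the 3 others had 92 to 148 genes at an unadjusted p under 0.05, against 213 in the real split and 435 to 1094 in the 6 that keep a pair together.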

How the results depend on the processing

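The GC correction (alone, with the block or without PL Dex library 3), the thinned counts and the fits without PL saline libraries 1 and 2 together were chosen after seeing the data, as was leaving out single libraries for the similarity of the effects; the other alternatives were not. For Dex in PL edgeR called 4 genes; it called 0 with RLE factors, 193 without the low-count filter (92 higher, 101 lower), 0 in a fit of the 6 libraries alone, 1 with the GC correction, 2 with it and the batch block, 0 with thinned counts, 7 without PL saline libraries 1 and 2, and 53 with the GC correction without PL Dex library 3. DESeq2 called 123 (48 higher, 75 lower) and left 7375 adjusted p undefined. Leaving out single libraries gave 0 to 1528, the latter without PL Dex library 3. Without PL Dex library 3 the GC correction took the count from 1528 to 53, so most of these calls went with GC content. The slope on GC was −0.104 in that library, against 0.126 and 0.117 in PL Dex libraries 1 and 2. Whether the trend came from a bias or from Dex stays open. Thinning and smaller fits leave fewer counts or samples. For the remaining changes the cause was not tested. Without the filter edgeR called 3 genes for Dex in IL (0 otherwise) and 4 for the difference of effects (0 otherwise), where leaving out single libraries gave 0 to 169 (without PL Dex library 3). Between the regions in saline mice 3737 genes were called, 1128 without PL saline libraries 1 and 2 and 1874 to 3275 without single libraries (lowest without PL saline library 2). In Dex mice 1469 were called, 2523 with the GC correction and batch block, and 793 to 1720 without single libraries (lowest without IL Dex library 2); the other alternatives kept both counts within 1.5 times. With both PL saline libraries left out, the remaining one was assumed to vary like the other groups.

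Srebf1 in PL (0.76) was past the threshold without the filter (0.766), in DESeq2 (0.768) and at the upper end of 0.603 to 0.903 over single libraries left out. Its difference of effects ran from 0.592 to 0.891 over them, the highest past the threshold without PL Dex library 3. Its value in IL changed sign, uncalled throughout, without the filter (−0.00188) and over single libraries (−0.0778 to 0.127), as did that of Phgdh in IL with the GC correction (0.0123), with correction and block (0.0135), with thinned counts (0.0559) and over single libraries (−0.103 to 0.0569). Between the regions in Dex mice both genes lost the call in a fit of 6 libraries (Srebf1 −0.506, Phgdh −0.505) and with the GC correction without PL Dex library 3 (−0.351 and −0.365), and Srebf1 with thinned counts (−0.519). Over single libraries Srebf1 ran from −0.663 to −0.364 and Phgdh from −0.657 to −0.366. The cause was not tested. Snhg14, higher in PL than IL in saline mice, turned to −0.0719 with the GC correction and −0.0724 with correction and block, uncalled.

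With an estimated correlation 0 lists were called in each of the 5 comparisons. For Dex in PL 5 lists were called, 8 without PL saline libraries 1 and 2 (3 of the 5 among them), and 4 to 9 without single libraries (9 without PL Dex library 2). In IL the 4 lists became 0 to 11. For the difference of effects the 4 lists became 7 with correction and block, 7 without PL saline libraries 1 and 2, and 0 to 5 without single libraries (0 without IL saline library 1). The similarity of the effects, 0.0537, was 0.0114 over genes of at least 10 CPM and −0.00373 to 0.0961 without single libraries. Of the 123 genes named for the regions in saline mice, 104 kept call and direction with the GC correction, 18 lost the call and 1 turned, and 54 lost it without PL saline libraries 1 and 2. Of the 98 in Dex mice 0 lost it with the GC correction, 12 with that correction without PL Dex library 3 and 14 in the fit of 6 libraries. With single libraries left out, 71 of 738 fits of these genes lost the call in saline mice and 120 of 588 in Dex mice. With the batch block 3 genes were called in PL, and it changed no call among the named genes and lists beyond those of Zfp942, Gm37895, Sh2d3c, Ndst4 and the glucocorticoid and mural lists given with their comparisons. Thinned to the depth of the smallest library, 5419187 counts, 3163 genes were called between the regions in saline mice and 1357 in Dex mice.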

Other observations

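The gene lists and their tests were fixed in advance, but which lists and genes are described here was chosen only after their results were seen.

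Of 11 measured genes of adrenergic receptors and transporters, 4 were called higher and 3 lower in prelimbic than in infralimbic cortex of saline mice, and the list as a whole was not called (adjusted p 0.678). Striatal markers moved between the regions in the same libraries (score difference −2.17 in saline and −2.33 in Dex mice). Among the lower genes, Adra2a was at 12.4 ± 2.64 against 30.5 ± 6.88 CPM (log2 fold change −1.32, SE 0.243, edgeR adjusted p 0.00149) and Adra2c at 9.80 ± 4.77 against 23.2 ± 1.65 CPM (−1.26, adjusted p 0.00183). Among the higher genes, Adra1a was at 58.8 ± 1.63 against 33.8 ± 4.64 CPM (0.80, adjusted p 0.000407) and Adra1d at 17.9 ± 7.29 against 7.63 ± 0.759 CPM (1.24, adjusted p 0.00124). In Dex mice Adra2a (−1.37, adjusted p 0.00202), Adra1d (1.39, adjusted p 0.00118) and Adra1a (0.73, adjusted p 0.0017) were called again. Adra2c (−0.92, adjusted p 0.025) was lost without IL Dex library 1 (0.0567) or 3 (0.114) or PL Dex library 1 (0.062), 2 (0.0844) or 3 (0.0856). Dex against saline in PL gave 0.14 for Adra2a (adjusted p 0.83) and 0.51 for Adra2c (adjusted p 0.381).

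Of the clock genes in PL, adjusted over the list alone, 3 of 21 were lower with Dex and 0 higher: Nr1d2 (−0.56, SE 0.103), the clock output gene Dbp (17.1 ± 5.5 against 28.5 ± 2.96 CPM, −0.74, SE 0.177) and the repressor gene Bhlhe41 (25.6 ± 1.59 against 36.6 ± 6.6 CPM, −0.51, SE 0.14). Per1 (0.42) and Arntl (0.30) were not called, and over all genes edgeR called 0 of the 21. The list had an adjusted p of 0.591, and of 0.025 in the direction of lower levels after the GC correction (adjusted p = 0.633 with an estimated correlation), in which its median was 0.01. Cholesterol genes had 3 of 27 members higher with Dex in PL, adjusted over the list alone, among them the transcription factor gene Srebf2 (0.41) and Scap, whose product escorts SREBP proteins (0.41). Among the astrocyte markers Gfap (64.1 ± 12.9 against 43.4 ± 7.81 CPM, 0.56, SE 0.158) and Fgfr3 (0.47, SE 0.109) were higher with Dex in PL, adjusted over the list alone. Neither list was called (adjusted p 0.196 and 0.551), nor was that of serine synthesis and transport (0.189), in which 0 of 18 members passed and Cbs had a value of 0.51.

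Some lists held members called in both directions between the regions. Among the upper-layer markers Lmo4 was higher in PL in saline mice (1.05, adjusted p 4.34e-05) and Plxnd1 lower (−1.12, adjusted p 4.34e-05), with 2 of 13 called higher and 3 lower and a list adjusted p of 0.733. Among the cAMP genes, with 6 of 21 called higher and 6 lower, the adenylyl cyclase gene Adcy1 was at 1290 ± 174 against 821 ± 73.7 CPM (0.65). Of the targets of insulin and FoxO signalling 1 of 21 was higher and 4 lower, among them Foxo1 itself (−1.07, adjusted p 0.00192). Lists called in none of the 5 comparisons included markers of microglia, endothelium, oligodendrocytes and their precursors, inflammatory genes, heat shock genes, hypoxia targets, ATF4 targets, cold-inducible genes, glutamate receptors and nuclear-retained RNAs. Their smallest adjusted p was 0.0637, for heat shock genes between the regions in saline mice. After the GC correction 4 of them were called in 1 comparison each: heat shock genes in the same comparison (0.0203), glutamate receptors (0.0265) and microglia (0.0393) for Dex in IL, and nuclear-retained RNAs for the difference of effects (0.0106). None of these 4 was called with an estimated correlation (adjusted p = 0.659, 0.636, 0.636 and 0.972 with an estimated correlation, after the GC correction).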
